A study of Mus musculus with 3 samples.

How the data were processed

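The series holds 3 microarrays of mouse endosteal cells, 1 for each sorted population, and each array's group was taken from its title in the labels. Per the labels' protocols, total RNA was extracted with TRIzol and biotin-labelled cRNA was made by a 2-cycle assay of the array's maker, which amplifies small amounts of RNA. The values analysed are the deposited signal intensities of 45101 probe sets per array on a linear scale, made by the authors with MAS5, per the submitters' processing notes; its version is not given in the sources used here. MAS5 condenses the probes of a probe set into 1 signal and scales an array by 1 factor. The 2% trimmed mean was 500 on each of the 3 arrays, so the deposited values already share a scale and were used without further scaling. Such scaling sets the total signal of the arrays equal, so a population with more RNA per cell or a wider range of transcripts cannot be told from its values, and amplification favours the 3' ends of transcripts. The ratio of the 3' to the 5' control probe set was 2.77, 2.55 and 2.77 for Actb and 3.75, 3.96 and 3.90 for Gapdh in ALCAM+, Sca-1+ and marker-negative cells. Control probe sets, 64 per array, entered no gene result. The precision is limited by the number of arrays, 1 per population.

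Gene names came from the array's annotation table, updated through the Entrez identifiers of a RefSeq gene table (assembly GRCm38.p6, used for names only), in which 34754 of 34958 identifiers were found and which changed 0 symbols. Of 45037 other probe sets 34958 had 1 gene symbol, 932 had several and were not used to name a gene, and 9147 were not listed and are unnamed here. That left 18194 genes, of which 9012 had more than 1 probe set. Genes of the fixed lists without a named probe set were not analysed here.

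Signals were raised to a floor, the pooled median of 75.4 over the non-control probe sets of the 3 arrays, and turned to log2. A gene was represented by its probe set with the highest mean signal, and was called measured if it lay above the floor on at least 1 array, as 12644 genes did. With 1 array per group there is no test between groups and no p-value. Genes were counted if they differed at least 4-fold, that is by at least 2 on the log2 scale, in the 3 comparisons between populations. Where the dimmer value lay at or below the floor, the fold against the floor is given as at least that size. Disagreement between 2 probe sets of the same gene, over 4154 genes with both above the floor on every array, had an SD on the log2 scale of 0.38, 0.47 and 0.53 in the 3 comparisons. This leaves out the spread between sorts and mice, which was not measured.

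The 32 gene lists, the named-gene rule, the design and the main alternatives were fixed before the data were examined. For each list the median log2 difference of its measured members was set against 10000 random lists of the same size, drawn from measured genes matched on mean log2 signal in 20 bins, and called higher above percentile 97.5 or lower below percentile 2.5, as a description of these arrays. List calls given without a number of alternatives held under at least 6; scaling to equal trimmed means, which moves nothing, is not counted. Named are the sorting genes, for each comparison and direction the genes with the largest differences above the floor on both arrays (up to 10) and the brightest genes whose dimmer value was at or below the floor (up to 5), and for each list up to 4 members with the largest differences, with all members at least 4-fold apart of the osteoblast, progenitor, niche factor, adhesion and cytokine lists; fewer are printed, in rank order within a part of the rule, apart from members named because they went against the rest of their list.

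The procedure was tested on simulated data for ALCAM+ against marker-negative cells, with a noise SD of 0.5 on the log2 scale. In each of 10 simulations 200 changed genes were drawn from genes more than 8-fold above the floor. Of genes changed 8-fold 92.5% passed 4-fold, and of genes changed 2-fold 7.3%. Recovery of dimmer genes was not tested. In a single simulation of 18194 genes, 0.436% of the unchanged genes above the floor passed 4-fold. That share follows from the assumed noise, set equal for dim and bright genes, and is not an error rate of these arrays. Of 100 unchanged lists of 20 genes from that simulation 3% were called apart, and of the same lists raised 2-fold 100%. Their members were random genes with independent noise, all more than 8-fold above the floor. These rates therefore do not hold for lists that are smaller, dimmer or made of genes that vary together. A first version of the recovery test, judged by a single simulation, fell short of its own bound and was replaced by the mean of 10.

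The alternatives were scaling to equal trimmed means, quantile normalization, floors at the pooled 25th percentile (21.1), at the pooled 75th (433.9) and at the 95th percentile of olfactory and vomeronasal receptor probe sets (62.4), the mean over all probe sets of a gene, leaving out probe sets whose names end in _x_at or _s_at, and a 2-fold rule. Scaling on the poly-A spike-in controls and on the hybridization controls was added after the control signals were seen. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.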

Results

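The series measured gene expression in 3 populations of endosteal cells, the cells that lie along the inner surface of bone, from C57BL/6 mice. Cells released by collagenase from thigh and shin bone fragments and free of CD45, CD31 and Ter119, the markers of blood cells, vessel lining and red cells, were sorted on ALCAM, an adhesion molecule, and Sca-1, a surface marker of stem and progenitor cells. The populations were ALCAM+ Sca-1- (called ALCAM+ here), ALCAM- Sca-1+ (called Sca-1+) and ALCAM- Sca-1- (called marker-negative). Each population was measured on 1 array, so there are no replicates, no difference has a replicate check, and the words higher and lower with a count of genes refer to a size rule of 4-fold and not to a test. The signal was above the floor of 75.4 for 49.7% of probe sets in ALCAM+, 48.9% in Sca-1+ and 51.4% in marker-negative cells. Control RNAs spiked in before labelling had a geometric mean signal of 938 on the ALCAM+ array, 494 on the Sca-1+ array and 627 on the marker-negative array, although the trimmed mean of each array was 500.

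Alcam had its highest signal in the ALCAM+ population in each of its 4 probe sets above the floor on any array, with 267.7 there against 41.1 in Sca-1+ and 36.3 in marker-negative cells for the brightest of them. Ptprc, which encodes CD45, gave 11.6 in ALCAM+, 163.2 in Sca-1+ and 159.4 in marker-negative cells, and its other probe set stayed below the floor on the 3 arrays. Pecam1, which encodes CD31, was below the floor on the 3 arrays, at 7.0, 5.2 and 9.1. The gene for Sca-1 was not analysed here.

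The first comparison set ALCAM+ against marker-negative cells, which asks what accompanies ALCAM among endosteal cells without Sca-1. Genes of bone-forming cells and of osteocytes, the cells enclosed in bone, were higher in ALCAM+ cells. Dmp1, a bone matrix protein gene of osteocytes, was 56.1-fold higher, at 6431 against 115, and Ifitm5, a bone-restricted membrane protein gene, was 24.3-fold higher, at 7744 against 319. Cdh2, which encodes N-cadherin, was 35.9-fold higher, at 6178 against 172. Genes of red cell development and of cell division were lower: Ctse was 78.5-fold lower in ALCAM+ cells, Car1, a red cell carbonic anhydrase gene, 49.9-fold and the proliferation marker Mki67 25.5-fold.

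Of the 16 measured osteoblast lineage genes, 3 were at least 4-fold higher in ALCAM+ cells (Ifitm5, Col22a1 at 17.5-fold and Kazald1 at 13.9-fold) and 0 lower, with a median log2 difference of 1.39 that stood apart from random lists. The osteocyte list had 5 of 8 genes higher and a median of 3.12, also apart. Besides Dmp1 these were Ptprz1 at at least 18.1-fold, Phex, a phosphate-regulating endopeptidase gene, at 14.3-fold, Irx5 at 12.6-fold and Dkk1 at 5.96-fold. Other genes of the osteoblast list that were bright in both populations differed less: Col1a1, the main bone collagen gene, had 49506 in ALCAM+ and 13081 in marker-negative cells (3.78-fold), Ibsp 37633 and 18264, and Alpl 24709.8 and 12905. Among 30 measured adhesion genes, Cdh2, Cdh15 (14.6-fold) and Cdh11 (14.5-fold) were higher, and the integrin genes Itga4 (at least 9.90-fold) and Itga8 (5.38-fold) were lower, while the list's median of 0.03 was within the range of random lists, which held under 5 of 8 alternatives. It lay above that range with the floor at the pooled 75th percentile (median 0.24) and under scaling on the poly-A spike-in or the hybridization controls, where its median was -0.07 and -0.06 and that of all measured genes -0.53 and -0.43.

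The chondrocyte list did not stand apart between these populations, with 2 genes higher, 2 lower and a median of 0.03 against a mean of -0.14. Its members split: Col10a1, the collagen of hypertrophic cartilage, was 4.19-fold higher in ALCAM+ cells and Matn1 4.18-fold higher, whereas Prg4, which encodes the joint lubricant lubricin, was 9.34-fold lower and Ucma 4.90-fold lower. The BMP and TGF-beta list was apart on the high side in ALCAM+ cells (median 0.47, 4 higher and 1 lower of 25), with Bambi, a decoy receptor gene, 8.31-fold higher, Smad6 6.63-fold higher and Gdf10 6.34-fold lower. That call held under 5 of 8 alternatives and was lost with 2 of the other floors and, with a median of -0.06, when all probe sets of a gene were averaged. The mesenchymal progenitor and fibroblast list (median -0.04) and the haematopoietic niche factor list (median -0.07) were not apart. Single members of them passed 4-fold: Pdgfra was 7.63-fold higher in ALCAM+ cells, Kitl, which encodes stem cell factor, at least 5.92-fold higher, Pgf at least 6.94-fold higher and Cd34 at least 5.67-fold lower. Also not apart were the Wnt list (median -0.04; Dkk1 and Nkd2, at 4.30-fold, were higher), the collagens (-0.02; Col24a1 was 10.4-fold higher and Col12a1 7.57-fold lower), the proteases and inhibitors (0.09; Mmp16 was 11.8-fold higher and Serpina3n 7.25-fold lower; within the random range under only 3 of 8 alternatives, with medians from 0 to 0.61, and above it under the other 5), the Notch genes (-0.15), complement (-0.29), interferon-stimulated genes (0.00) and immediate early genes (0.18).

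The cell cycle list was the group with the most members apart: 19 of 22 genes were lower in ALCAM+ cells, with a median of -3.38. Ccna2 was at least 29.0-fold lower, Mki67 25.5-fold and Mcm5, a replication helicase gene, 22.2-fold. The erythroid list moved with it, with 8 of 11 genes lower and a median of -2.26. Klf1, a transcription factor gene of red cell precursors, was at least 48.4-fold lower in ALCAM+ cells, with 3649 in marker-negative cells, Ermap at least 49.9-fold lower and Slc4a1 at least 32.0-fold lower. The cytokine and chemokine list was lower in ALCAM+ cells (median -0.69, 4 of 25 lower), with Il33 at least 6.91-fold, Il6 4.96-fold, Csf2 at least 4.48-fold and Cxcl2 at least 4.41-fold lower. That call held under 5 of 8 alternatives: the median was within the range of random lists with the floor at the pooled 75th percentile (median 0) and under either spike-in scaling (medians -0.76 and -0.69).

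Over all genes, 254 were at least 4-fold higher in ALCAM+ than in marker-negative cells and 338 lower, out of 12644 genes above the floor on at least 1 array. After Dmp1 the genes with the largest differences above the floor on both arrays were Mlip (41.6-fold), Chn1 (40.9-fold), Cdh2, Prss35 (32.8-fold) and Slc36a2 (30.2-fold), and after Ctse and Car1 those lower were Mki67, Cdca8 (23.8-fold), Mcm5 and Cldn13 (21.2-fold). Of the genes with another probe set above the floor, all others pointed the same way for 97.0% of the 134 higher and 95.8% of the 144 lower genes. Another probe set reached 2-fold in that direction for only 76.1% and 68.1% of them. Scaled on the poly-A spike-in controls, the split became 151 higher and 619 lower, and on the hybridization controls 165 and 542. The balance turned to 122 higher and 86 lower with the floor at the pooled 75th percentile, the lower genes rose to 584 with the 25th, and averaging probe sets gave 168 and 194.

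**Figure D1:**
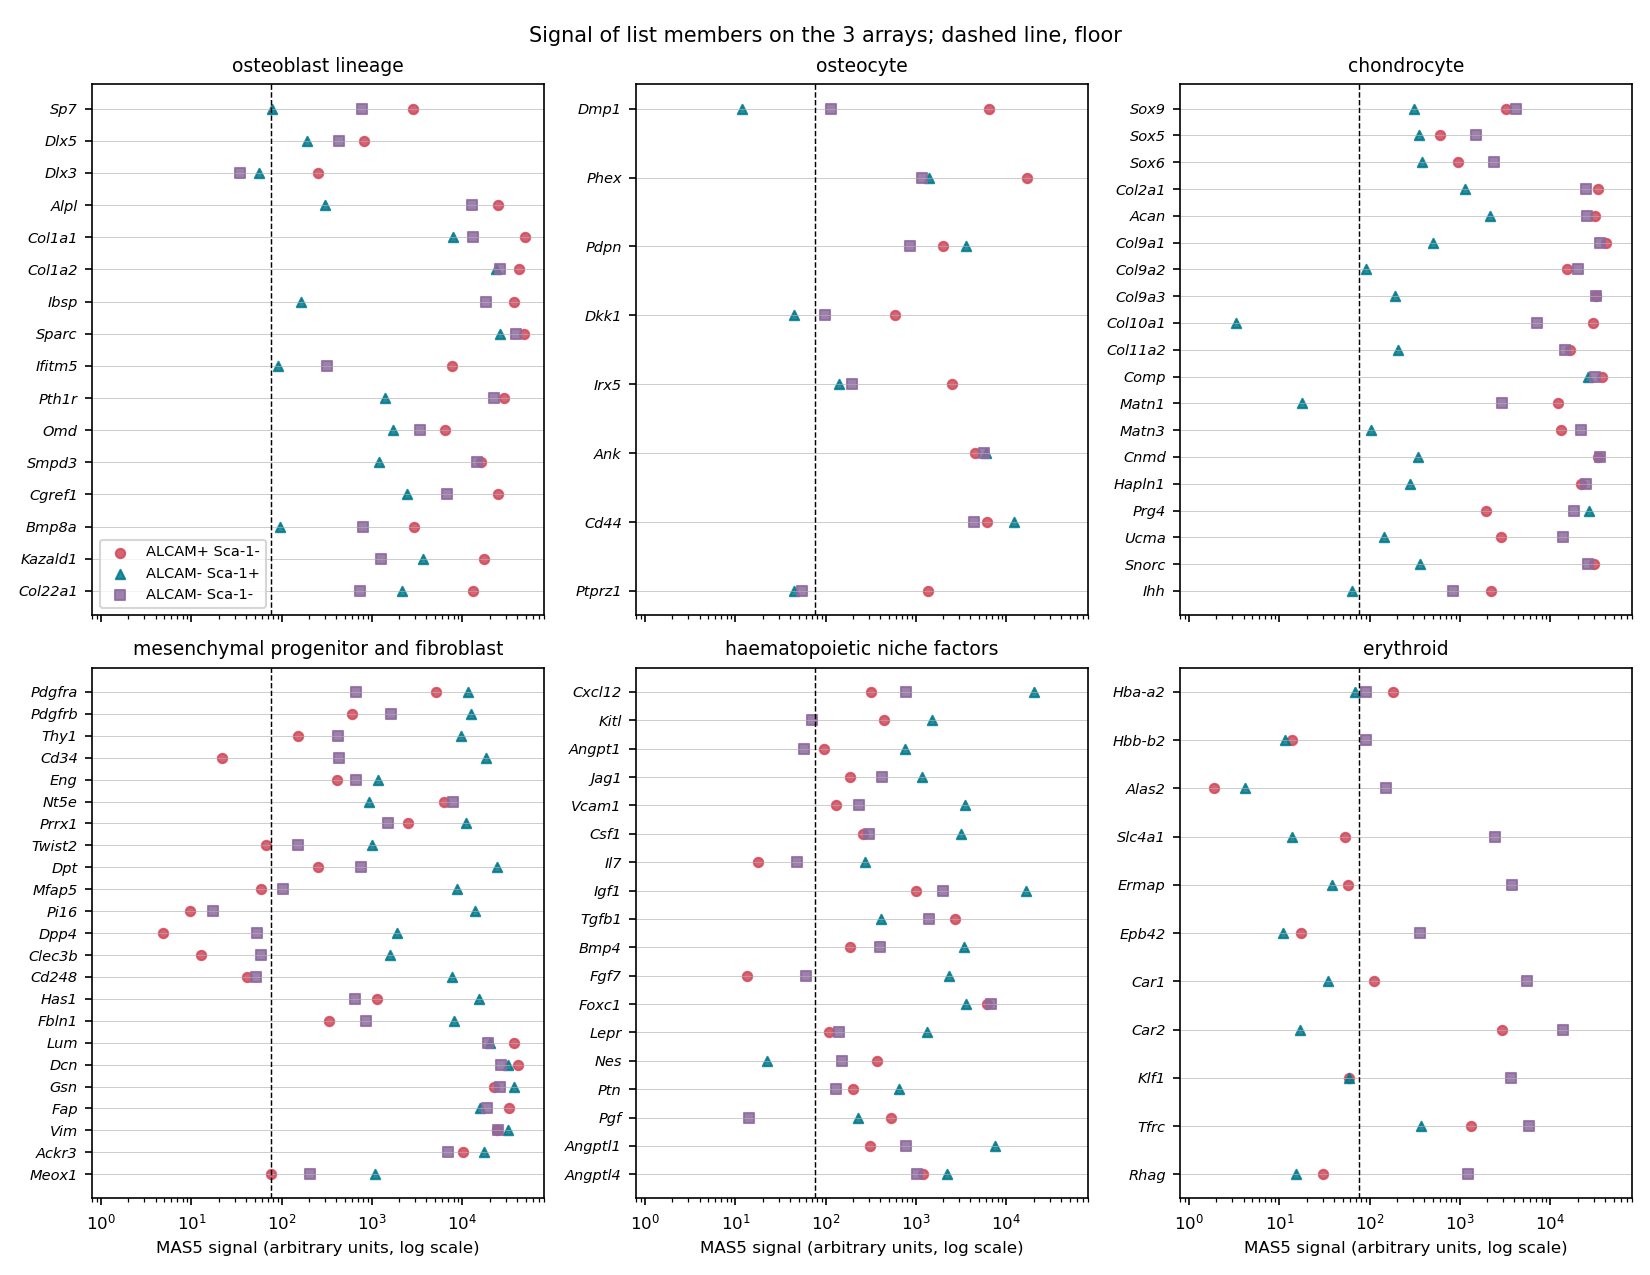
Signal on a log axis (arbitrary units) of the measured members of 6 gene lists on the 3 arrays, 1 point per gene and array, with the floor of 75.4 as a dashed line. Col10a1 lies at 29730 in ALCAM+ and 3.30 in Sca-1+ cells, Cxcl12 at 20123 in Sca-1+ and 319.7 in ALCAM+ cells, and Klf1 at 3649 in marker-negative cells.

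The second comparison set Sca-1+ against marker-negative cells, which asks what accompanies Sca-1 among endosteal cells without ALCAM. Genes of fibroblasts and mesenchymal progenitors, of factors that act on blood-forming cells, of chemokines and of complement were higher in Sca-1+ cells, and genes of cartilage and bone were lower. Pi16 was at least 182-fold higher, at 13721 against 17.3, and Cd34, a surface marker of progenitors, 43.2-fold higher, at 18453 against 427. Cxcl12, the chemokine gene that holds stem cells in marrow, was 25.9-fold higher, at 20123 against 778. Col9a2, a cartilage collagen gene, was 219-fold lower in Sca-1+ cells, Matn3 212-fold lower and the bone matrix gene Ibsp 113-fold lower.

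In the mesenchymal progenitor and fibroblast list 15 of 23 measured genes were at least 4-fold higher in Sca-1+ cells and 1 was lower (Nt5e, 8.33-fold), with a median of 2.94. After Pi16 came Cd248 at at least 103-fold, Mfap5 at 84.1-fold, Cd34, Dpt at 32.7-fold, Dpp4 at at least 24.9-fold, Has1 at 23.7-fold, Thy1 at 22.9-fold, Clec3b at at least 21.1-fold and Pdgfra at 17.3-fold. The haematopoietic niche factor list had 11 of 18 genes higher, 0 lower and a median of 3.07. Besides Cxcl12 these were Fgf7 at at least 30.8-fold, Kitl at at least 20.1-fold, Vcam1 at 14.7-fold, Csf1 at 10.2-fold, Angpt1, which encodes a ligand of the Tie2 receptor, at at least 10.1-fold, Angptl1 at 9.64-fold, Lepr at 9.51-fold, Bmp4 at 8.58-fold, Igf1 at 8.23-fold and Ptn at 4.96-fold, though its other probe set pointed the opposite way. The adhesion list was apart on the high side (median 0.47), with Itgb3 (at least 22.7-fold), Postn (15.4-fold), Vcam1, Cdh13 (14.0-fold) and Jam2 higher and Itga4 (at least 9.90-fold) and Itga10 (4.96-fold) lower. Jam2 was 5.12-fold higher, but 2 of its 3 other probe sets pointed the opposite way.

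Cytokine and chemokine genes were higher in Sca-1+ cells, with 9 of 25 at least 4-fold higher, 3 lower and a median of 1.58. The eosinophil attractant gene Ccl11 was at least 41.0-fold higher, Ccl7 at least 28.8-fold and the monocyte attractant gene Ccl2 27.0-fold, Cxcl2 12.1-fold, Ccl8 11.7-fold and Il33 9.85-fold, whereas Lif was 7.54-fold lower, Il11 at least 5.57-fold and Csf2 at least 4.48-fold. The complement and acute phase list had 6 of 8 genes higher and a median of 4.05, led by Cfb (35.7-fold), C1s1 (26.9-fold), Lcn2 (at least 23.6-fold) and C1ra (18.0-fold). Lcn2 is also a granule gene of neutrophils, and the neutrophil list moved the same way, with 7 of 14 genes higher, 3 lower and a median of 2.29. Ngp was 28.6-fold higher in Sca-1+ cells and Camp at least 20.9-fold, whereas Mpo, a gene of early granulocytes named here after its values were seen, was 14.8-fold lower. Interferon-stimulated genes were higher (median 1.05, 5 of 20 at least 4-fold, among them Gbp2 at 13.9-fold and Psmb8 at at least 12.2-fold), as were the proteases and inhibitors (median 1.44, 7 of 22, with Adamts12 at 9.62-fold and Serpina3n at 7.87-fold). The Wnt list was apart with a median of 1.00, but its members went both ways, 7 higher and 6 lower of 25. The Wnt modulators Dkk2 (55.5-fold), Rspo2 (at least 50.7-fold) and Sfrp1 (31.1-fold) were higher in Sca-1+ cells and the ligand gene Wnt4 was at least 47.6-fold lower.

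The chondrocyte list had 17 of 19 genes lower in Sca-1+ cells and a median of -6.13. Col9a2 and Matn3 led it, followed by Col9a3 (167-fold) and Cnmd (102-fold). In the osteoblast lineage list 6 of 16 genes were lower and 0 higher, with a median of -1.32. Besides Ibsp these included Alpl, the bone alkaline phosphatase gene, at 43.1-fold, the parathyroid hormone receptor gene Pth1r at 16.2-fold and the sphingomyelinase gene Smpd3 at 12.2-fold. The osteocyte list was not apart (median 0.04, with Pdpn 4.14-fold higher). Cell cycle genes were lower in Sca-1+ cells in 19 of 22 cases (median -3.55, Mki67 33.7-fold). Beside them the erythroid list had 8 of 11 genes lower and a median of -4.03 (Car2 at least 182-fold and Car1 at least 72.8-fold). Unlike the median erythroid gene, Car2 was well above the floor in ALCAM+ cells too, at 2879 against 13751 in marker-negative cells. The collagens (median 0.13, a call that held under 5 of 8 alternatives), the Notch genes (0.54), the immediate early genes (-0.27) and the BMP and TGF-beta list (median -0.34, mean 0.07) were not apart. Collagens split, with Col5a3 23.7-fold and Col14a1 34.1-fold higher and Col11a1 21.4-fold and Col11a2 70.0-fold lower.

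In all, 690 genes were at least 4-fold higher in Sca-1+ than in marker-negative cells and 595 lower, which became 345 and 223 with the floor at the pooled 75th percentile and, for the higher genes, 459 with probe sets averaged. The largest differences above the floor on both arrays were those of Mfap5, Scara5 (67.4-fold), Dkk2 and Efhd1 (55.4-fold) on the high side and of Col9a2, Matn3, Mia (177-fold) and Col9a3 on the low side. All other probe sets pointed the same way for 318 of 342 higher and 278 of 285 lower genes that had them. Another probe set reached 2-fold in that direction for 82.5% and 79.6% of them.

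The third comparison set ALCAM+ against Sca-1+ cells, the populations that carry 1 of the sorting markers each. It is the difference of the first and second comparisons and adds no independent measurement. Cartilage and bone genes were higher in ALCAM+ cells and the fibroblast, niche, chemokine and complement genes were lower. Col10a1 was at least 394-fold higher, at 29730 against 3.30, Ibsp 233-fold higher and Alpl 82.5-fold higher. Cd34 was at least 245-fold lower, Tnxb, which encodes a connective tissue tenascin, 129-fold lower and Cxcl12 62.9-fold lower, at 319.7 against 20123.

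All of the called osteoblast lineage genes, 12 of 16, were higher in ALCAM+ cells (median 2.99), led by Ibsp, Ifitm5 (85.9-fold), Alpl and Sp7 (36.9-fold). The osteocyte list had 5 of 8 higher and a median of 3.28, with Dmp1 at least 85.3-fold higher. The chondrocyte list had 15 of 19 higher, 1 lower (Prg4, 13.7-fold, named after its value was seen) and a median of 6.30, and Car3, assigned here to the adipogenic list, was at least 615-fold higher. Among adhesion genes, Cdh2 was at least 81.9-fold higher in ALCAM+ cells, Cdh15 at least 19.3-fold and Cdh11 7.46-fold, and Cdh13, which encodes T-cadherin, was 29.8-fold lower. The integrin genes Itga10 (8.41-fold) and Itga1 (4.66-fold) were higher and Itgb3 (at least 22.7-fold) and Itga8 (5.41-fold) were lower, as were Vcam1 (26.4-fold), Postn (13.0-fold) and Icam1 (9.37-fold). The adhesion list as a whole was not apart (median -0.30), though it was called lower after quantile normalization (median -0.40).

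On the other side, 14 of 23 progenitor and fibroblast genes were lower in ALCAM+ cells (median -3.73; Pi16, at least 182-fold; Mfap5, at least 116-fold) and Nt5e was 6.67-fold higher. Among niche factors 10 of 18 were lower and 2 higher (median -2.82). Fgf7 was at least 30.8-fold lower, Angptl1 24.0-fold and Bmp4 18.2-fold, and Tgfb1 was 6.60-fold higher. Nes was also at least 4.89-fold higher, but its other probe set pointed the opposite way and the direction turned under either spike-in scaling (log2 difference -1.46 or -1.39). Cytokine and chemokine genes were lower in 13 of 25 cases and higher in 0 (median -2.005), led by Il33 (at least 68.1-fold), Cxcl2 (at least 53.2-fold) and Ccl11 (at least 41.0-fold). Complement and acute phase genes were lower in 7 of 8 cases (median -4.55; Cfb, at least 44.3-fold), and the neutrophil list, which shares Lcn2 with it, in 7 of 14 (median -2.80; S100a8, 63.4-fold). Also lower as lists were the interferon-stimulated genes (median -1.65, 9 of 20), the proteases and inhibitors (-1.10, with Serpina3n 57.0-fold and Plat 23.8-fold lower and Mmp13, a collagenase gene, 13.0-fold higher) and the Wnt list (-1.04), whose members again went both ways, with Frzb at least 107-fold higher and Dkk2 at least 82.1-fold lower. The collagens (median 0.01, mean -0.13) and the BMP and TGF-beta list (0.34) were not apart while single members differed, such as Col14a1 (111-fold lower), Col11a2 (79.9-fold higher), Col13a1 (48.5-fold higher) and Bmp8a (30.6-fold higher). Neither the Notch genes (-0.26) nor the cell cycle genes (0.04, 0 of 22 at least 4-fold apart) stood apart. The immediate early and stress genes had a median of 0.58 that was apart, with 0 genes at least 4-fold apart, and the call held under 6 of 8 alternatives, being lost after quantile normalization (median 0.23) and when probe sets were averaged.

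In total 504 genes were at least 4-fold higher in ALCAM+ than in Sca-1+ cells and 741 lower, and scaling on the poly-A spike-in controls turned this into 265 and 1679, on the hybridization controls into 296 and 1403, and the floor at the pooled 75th percentile into 256 and 356. Car3, Col10a1, Prss35 (at least 223-fold) and Panx3 (at least 210.3-fold) were the brightest of the higher genes that lay at or below the floor in Sca-1+ cells. The largest differences above the floor on both arrays on the low side were those of Tnxb, Col14a1, Itih5 (98.8-fold) and Dpt (96.0-fold). All other probe sets pointed the same way for 97.6% of 251 higher and 93.6% of 346 lower genes. Another probe set reached 2-fold in that direction for 84.1% and 80.3% of them. Genes at least 4-fold above both other populations numbered 138 in ALCAM+, 510 in Sca-1+ and 205 in marker-negative cells. The first pair became 75 and 832 when scaled on the poly-A controls and 82 and 781 on the hybridization controls, the last became 118 with probe sets averaged, and the 3 became 79, 270 and 49 with the floor at the pooled 75th percentile.

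**Figure D2:**
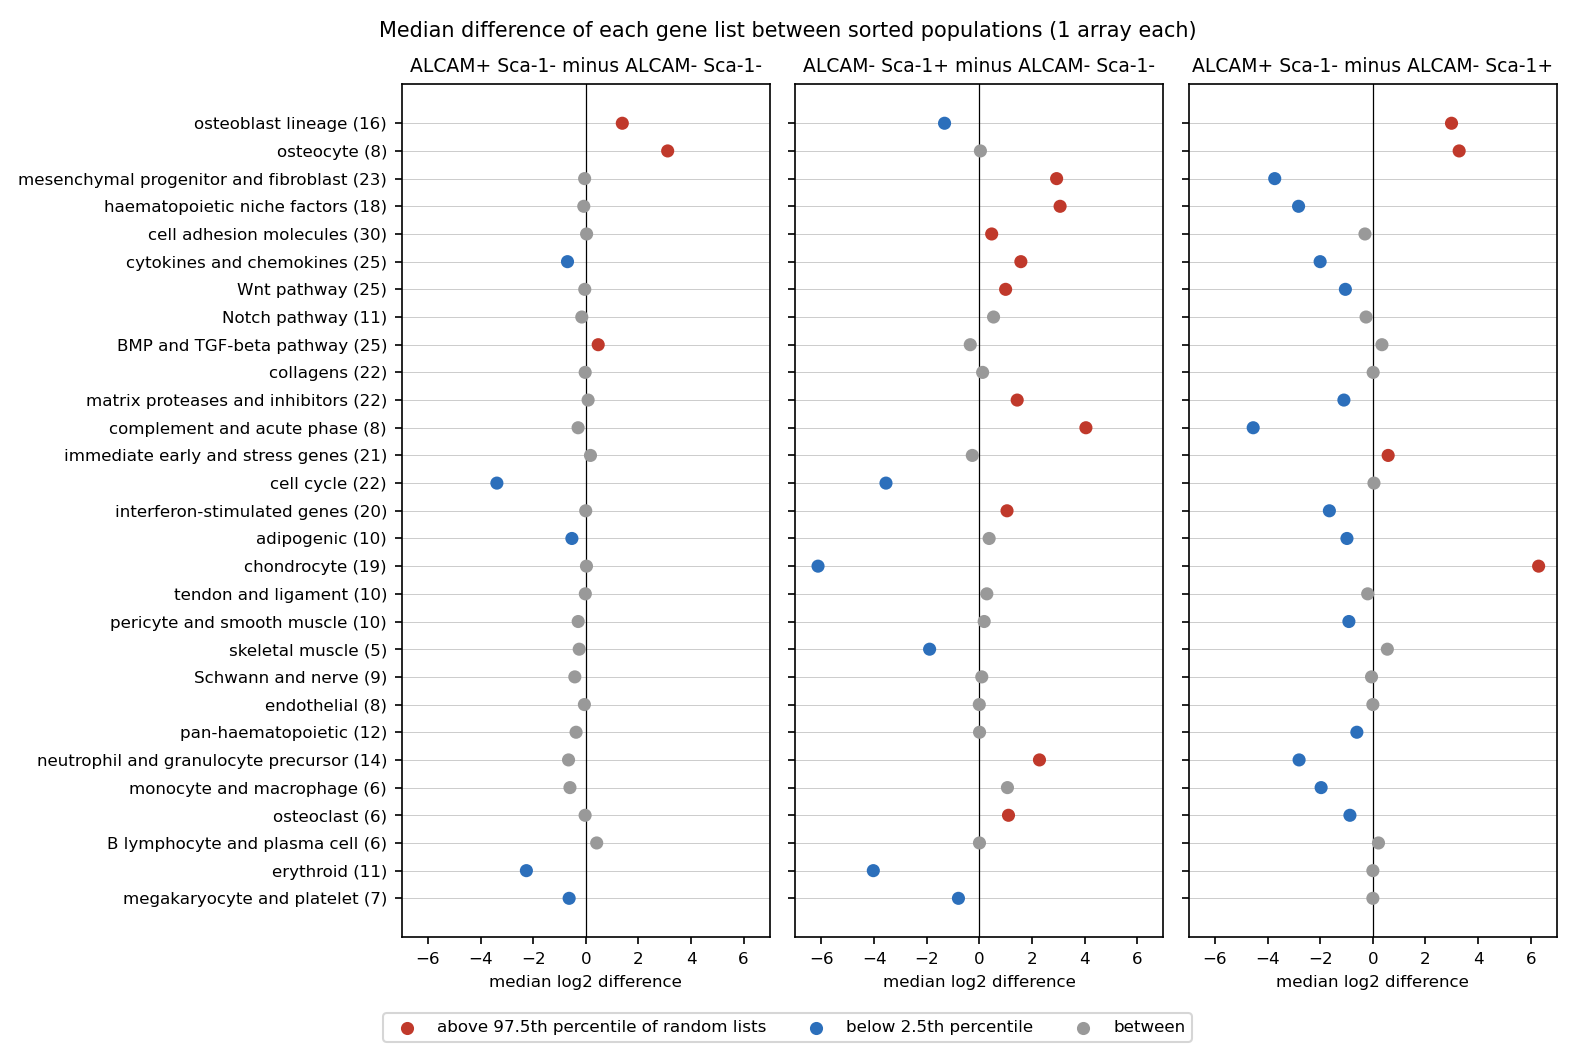
Median log2 difference (x axis) of each fixed gene list with at least 5 measured members, given in parentheses, in the 3 comparisons; red marks medians called higher, blue those called lower and grey the rest, against 10000 random lists matched on mean signal. The chondrocyte list lies at -6.13 in Sca-1+ against marker-negative cells and at 6.30 in ALCAM+ against Sca-1+ cells, and the cell cycle list at -3.38 and -3.55 in the comparisons with marker-negative cells.

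Lists of other cell types were described in the same way, given here in the order of the 3 comparisons. The adipogenic list had medians of -0.53, 0.37 and -0.98, called lower in the first, which held under 4 of 8 alternatives, and in the third. Car3 went against both calls, as the only member past 4-fold in the first (6.28-fold higher) and at least 615-fold higher in the third, and in Sca-1+ against marker-negative cells it was at least 97.9-fold lower and the lipase gene Lpl 11.7-fold higher. The pericyte and smooth muscle list (-0.29, 0.19 and -0.91) was called lower in the third, which held under 5 of 8 alternatives, with Rgs5 at least 30.9-fold lower, and Tagln was 9.34-fold lower and Abcc9 6.25-fold higher in ALCAM+ than in marker-negative cells. In Sca-1+ against marker-negative cells Abcc9 (15.2-fold), Rgs5 (8.45-fold) and Kcnj8 (at least 6.55-fold) were higher and Tagln 8.06-fold lower. Of 16 skeletal muscle genes 5 were measured (-0.25, -1.89 and 0.55), called lower in the second, which held under 7 of 8 alternatives, with Tnni2 at least 30.3-fold lower. The list was not apart in the third, which held under only 3 of 8 alternatives (medians 0 to 1.31). The tendon list (-0.02, 0.29 and -0.20), the Schwann and nerve list (-0.41, 0.09 and -0.05) and the endothelial list (-0.05, 0.00 and 0.00) were not apart in any, although Tek, which encodes Tie2, was at least 8.36-fold higher in Sca-1+ than in marker-negative cells.

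Among blood cell lists, the pan-haematopoietic list (-0.37, 0.01 and -0.61) was called lower in the third comparison only, and so was the monocyte and macrophage list (-0.60, 1.07 and -1.97; Lyz1, at least 37.4-fold), of which 6 of 16 genes were measured. The pan-haematopoietic call held under 2 of 8 alternatives and the monocyte call under 5. The osteoclast list (-0.02, 1.11 and -0.87) was called higher in the second and lower in the third comparison and rested on 6 genes, of which Itgb3 alone passed 4-fold; its call in the third held under 4 of 8 alternatives. The megakaryocyte list (-0.63, -0.79 and 0.00) was called lower in the first, which held under 6 of 8 alternatives, and in the second, which held under 7, although Itga2b was 5.17-fold higher in Sca-1+ cells. The neutrophil list was not apart in the first comparison (median -0.65), which held under 5 of 8 alternatives, nor the erythroid list in the third (0.00). The B cell list (0.42, 0.01 and 0.21) was not apart in any comparison, which held in the first under 5 of 8 alternatives, with Ebf1 24.9-fold higher in Sca-1+ than in marker-negative cells. The T and natural killer cell list (-0.11, -0.28 and 0.17) and the mast cell list (-0.27, -1.26 and 0.99) had 2 measured genes each and were not apart, which held for the mast cell list in the third under 4 of 7 alternatives.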

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

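Scaling on the poly-A spike-in or the hybridization controls was chosen after the control signals were seen; the other alternatives were planned. No paired analysis was possible because each population has 1 array and the labels give no replicate numbers, and for the same reason no other splits of the samples could be made. Scaling to equal trimmed means moved nothing, since the arrays already shared that scale, and says nothing about stability. Over the other alternatives 685 list medians kept their side of the random-list range, 39 newly passed it, 32 no longer did and 3 turned. Of the gene counts 46 stayed within 1.5 times and 35 did not. Of the log2 differences of genes picked by the naming rule, 5004 stayed within the SD between probe sets of a gene, 1675 moved by more and 2 turned. Turning was counted only for differences of at least 4-fold in the main setting. Smaller differences that changed sign are within the other numbers and were not counted apart. The floor at the pooled 75th percentile moved 461 of the log2 differences, the poly-A scaling 377 and the hybridization scaling 367. In the order ALCAM+ against marker-negative, Sca-1+ against marker-negative and ALCAM+ against Sca-1+, higher and lower each time, the floor at the pooled 75th percentile gave 122 and 86, 345 and 223, 256 and 356 genes at least 4-fold apart, with 79, 270 and 49 genes above both others in ALCAM+, Sca-1+ and marker-negative cells. A higher floor shrinks differences of dim genes by construction. The 2-fold rule gave 845 and 1339, 1894 and 1606, 1416 and 1999, and 445, 1338 and 655 above both others. The floor at the pooled 25th percentile gave 584 lower in the first comparison. The mean over probe sets gave 168 and 194 in the first, 459 higher in the second and 118 above both others in marker-negative cells. The poly-A controls gave 151 and 619 in the first, 265 and 1679 in the third, and 75 and 832 above both others in ALCAM+ and Sca-1+ cells, and the hybridization controls gave 165 and 542, 296 and 1403, and 82 and 781. These scalings shift all measured genes, with medians of -0.53, 0.29 and -0.87 (poly-A) and -0.43, 0.25 and -0.72 (hybridization) in the 3 comparisons, against which list calls were made. Among lists, adhesion genes became lower in the third comparison after quantile normalization (-0.40) and higher in the first with the 75th percentile floor (0.24) and under the poly-A (-0.066) and hybridization (-0.060) scalings. Progenitor genes became lower in the first with the 25th percentile floor (-0.32). Cytokines were no longer apart in the first with the 75th percentile floor (0) and under the poly-A (-0.76) and hybridization (-0.69) scalings. Calls that turned side were the B cell list in the first comparison with the 25th percentile floor (-0.70) and in the third with the 75th (-2.03), and the Schwann list in the first without _x_at and _s_at probe sets (0.52); none of these was apart in the main setting. Nes in the third turned under the poly-A (-1.46) and hybridization (-1.39) scalings, where another of its probe sets becomes the brighter. Apart from the higher floor and Nes, the cause was not tested. Signals near the floor limit every fold given as at least a size.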

Other observations

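The gene families and haemoglobin probe sets in this part, and the tests on the origin of the cycling transcripts, on a single kind of granulocyte and on carry-over of Sca-1+ type cells, were chosen after the results they bear on were seen. The genes named as insulin-like growth factor binding proteins had 5 measured members. Of these 4 were at least 4-fold higher in Sca-1+ than in marker-negative cells. All 5 were at least 4-fold lower in ALCAM+ than in Sca-1+ cells. Both counts held under quantile normalization and both spike-in scalings too. Igfbp5 had 626 in ALCAM+, 19854 in Sca-1+ and 3528 in marker-negative cells, and Igfbp6 949, 22942 and 5474. Igfbp7 was below 4-fold between Sca-1+ and marker-negative cells, at 23660.4 and 15762. Of 5 measured Adamtsl genes, matrix proteins related to the ADAMTS proteases, 4 were higher in Sca-1+ than in either other population under each scaling, among them Adamtsl4 at 4391 against 105 in ALCAM+ and 511 in marker-negative cells.

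Semaphorins, guidance molecules of axons and vessels, went both ways among 18 measured genes: 5 were higher in ALCAM+ than in Sca-1+ cells and 3 lower. Sema4d was 15.0-fold higher, at 2747 against 184, and Sema3c was 9.30-fold lower, at 1074 against 9997, and on the spike-in scalings the numbers became 1 higher and 5 lower. Of 24 measured Cyp genes 5 were higher in Sca-1+ than in both other populations, among them Cyp1b1, an oxidase of steroids and retinoids, at least 74.2-fold and Cyp2f2 28.8-fold above marker-negative cells, and these 5 stayed so on each scaling.

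Erythroid and cell cycle genes were highest in marker-negative cells although the sort removed cells with Ter119 and CD45. Scaling of the arrays does not account for it, since the erythroid list lay at least 2.84 (log2) above each other array on the poly-A spike-in scale. On the deposited scale its medians were -2.26 for ALCAM+ and -4.03 for Sca-1+ against marker-negative cells, so the poly-A scaling widened the smaller gap. Erythroid cells may be in this population: of 26 further erythroid genes 24 were measured, and their median was 1.84 higher than in Sca-1+ and 2.19 higher than in ALCAM+ cells. Gata1 lay at 1556 against 22.9 in ALCAM+ and 51.1 in Sca-1+ cells. The stage of such cells was not tested, so early ones, which carry little Ter119, cannot be told from later ones. The 4 probe sets that list several haemoglobin genes had a median of 11032 in marker-negative, 261.5 in ALCAM+ and 70.6 in Sca-1+ cells, but a probe set that lists Hba-a2 only was dim and highest in ALCAM+ cells, at 182 against 91.6 in marker-negative and 68.0 in Sca-1+ cells. Whether the cycling transcripts come from the erythroid cells and not from cycling skeletal cells cannot be told apart, because both sets of genes rise on the same array and 0 of 22 cell cycle genes were at least 4-fold apart between the other arrays, where the median erythroid gene was at the floor.

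Granulocyte genes split between the populations without ALCAM: in Sca-1+ against marker-negative cells the 9 late granule genes of the neutrophil list had a median of 3.89 (lowest 1.20) and its 4 early ones, Elane, Mpo, Prtn3 and Ctsg, -2.48 (highest -1.83). Scaling on the poly-A spike-in controls kept the signs opposite (4.30 and -2.26), and opposite signs argue against 1 kind of granulocyte in different amounts as the only source of these genes, although they are the genes in which the split was seen. The test first planned for it used 7 measured early genes outside the lists and gave 0.60, the sign of the late genes, with 4 members up and 2 down (Gstm1 3.36, Myb -2.69), so that on those genes the split does not appear. Mature granulocytes in the Sca-1+ sort, despite the removal of CD45 cells, stay open: of 14 further late genes with a named probe set the 9 measured had a median of 0.83, but 4 of these were at the floor in marker-negative cells and could only rise, and with the 5 at the floor on every array counted as 0, a reading added after the value was seen, the median was 0.26. The 5 above the floor in both populations had a median of 1.05 with 0 at least 4-fold apart, and expression of late granule genes by Sca-1+ cells themselves was not tested. Of the 9 measured, 3 (Fpr2, Trem1 and Mxd1) were also higher in ALCAM+ than in marker-negative cells and 2 were lower.

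Single cartilage genes differed between ALCAM+ and marker-negative cells, while the chondrocyte list as a whole did not stand apart (median 0.03, 2 higher and 2 lower of 19). Marker-negative cells may hold more articular or resting cartilage cells, since 11 further genes of these had a median 1.67 higher there (quartiles 0.80 and 2.40), although Cilp, Cilp2, Clu and Abi3bp, the 4 at least 4-fold higher, were also bright in Sca-1+ cells. Gas1, whose value is the median, was brighter in Sca-1+ than in marker-negative cells, at 16696 against 3049, while 7 of the 11 were dimmer in Sca-1+ cells. Carry-over of Sca-1+ type cells would need 27.4 to 82.8% of the Sca-1+ signal to explain the 4 genes at least 4-fold higher. The other articular genes were not set against it. A set of 14 progenitor genes was picked as at least 4-fold higher in Sca-1+ than in ALCAM+ cells, without regard to marker-negative cells. They reached a median of 3.94% (upper quartile 12.4%, highest 19.3%) in marker-negative cells. All 14 had already been seen at least 4-fold higher in Sca-1+ than in marker-negative cells, so low percentages were known beforehand. Of all 23 measured progenitor genes 15 lay below the lowest need. For those 4 articular genes the values argue against carry-over as the source but leave a subset of Sca-1+ cells untested. For more hypertrophic cartilage cells in ALCAM+ cells, 8 further genes had a median of -0.049. By the rule set beforehand, a median below 0.5 counts against that explanation. The members went both ways, with 4 up and 4 down and quartiles of -1.59 and 0.86, so the bound of 0.5 lies within their spread. A reading by quartiles, adopted after the value was seen, leaves the question open.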
